A study of Mus musculus with 18 samples.

How the data were processed

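Contacts of the Ifng and Il4 genes were measured in mouse cells by 4C on 18 NimbleGen-type arrays, 10 for Ifng and 8 for Il4, each with 384942 probes. Groups and replicate numbers came from the sample titles and source names, giving 9 groups of 2 arrays. Per the labels' protocols, chromatin was cut with HindIII and ligated, cut again with Csp6I and ligated, amplified by inverse PCR from the bait and labelled with Cy5, and genomic DNA of the same cells cut with both enzymes was labelled with Cy3. The deposited values are log2 ratios of Cy5 over Cy3 per probe. The base of the logarithm is not given in the sources used here and was taken as 2, and so are the scanner software, background correction, filters and genome build not given there. The values come in steps of 0.005, and in 7 of the 9 replicate pairs the sorted values of both arrays are equal within 0.011 for nearly all probes. A quantile step within a pair before deposit would give this, but that step is inferred from the values alone. The Ifng Th1 pair (42.8% of sorted values within that tolerance) and the Il4 Th2 pair (10.8%) are the exceptions.

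Some labels do not match the samples. The protocol describes adherent cells and names baits other than Ifng and Il4, the 3T3-L1 arrays carry a T cell characteristic, and the design text counts an array made from a pool without saying which. Titles and source names were followed, and that pooled array, if it is among the 18, was treated like the others. The build was found from the probe positions: with mm8 chromosome ends 0 of 21 chromosomes had a probe past the end and the largest gap was 125 kb, against 15 chromosomes for mm7, 5 for mm9 and 8 for mm10. Coordinates are in mm8 as inferred that way. Gene symbols and neighbours came from a RefSeq table of GRCm38.p6, another build, so genes were placed only in cytogenetic bands (bands of circlize 0.4.16), with genes near a band's edge left out, and a gene named with a band need not lie in the bin that changed. The lists of genes were planned on bins, which needed an annotation of the array's build, and were run on 383 bands instead, a choice made after the data were seen.

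Each array was centred on the median of its probes off the bait chromosome, with no loess or quantile step, and averaged in 500-kb bins with at least 20 probes. Bins within 1 Mb of the bait were left out. Bins were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with all groups of a bait in the fit, two-sided, and Benjamini-Hochberg adjustment over all bins of a comparison at 0.05. The test of the bait difference fitted both baits together. Adjacent called bins of the same direction were merged into regions, whose change is the mean over their bins while the SE and the adjusted p are those of the best bin. By a rule fixed before the data were examined, the regions named are at most the 5 with the largest mean change in each direction among called bins in which the arrays of the compared groups do not overlap, or, where fewer than 5 bins pass, the 3 bins with the smallest p in each direction, named as not passing. The same rule names 10 landmark genes (Ifng, Il4, Tbx21, Gata3, Stat4, Stat6, Il12rb2, Il4ra, Runx3 and Maf). Calls of contacts counted an array's highest 5% of probes per bin in a one-sided binomial test with adjustment over bins. Lists (Th1 programme, Th2 programme, naive and pan-T, JAK-STAT and SOCS, activation and cell cycle, Th17 and Treg, fibroblast and adipocyte, B cell, myeloid and NK, neuronal, housekeeping) were tested with camera in limma. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

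The fits were tested on simulated data in which 200 bins were changed. At a change of 0.4 the share recovered was 100% for the Ifng comparison of Th1 with naive cells and 97.0% for that of Il4, at 0.2 it was 73.1% and 25.4%, and for the bait difference it was 86.6% at 0.4 and 13.4% at 0.2. Of all calls in these simulations 7.61%, 5.13% and 3.62% were false. The simulated noise was independent between bins and of equal spread in all arrays of a fit. The spread of bins off the bait chromosome differed up to 2.78 times between the real Ifng arrays. These rates therefore need not hold for the real calls. Array precision is limited by their number. Leading digits of the array serial number, called serial series here, were used as a possible batch.

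Alternatives were other bin sizes (200 and 1000 kb), the median per bin, the share of the highest probes per bin, quantile normalization, scaling by the median absolute deviation of the bins off the bait chromosome, eBayes with trend and robust settings, the replicate number or the serial series as a block, the compared groups alone in the fit, the bait chromosome left out, extreme probes left out, and each replicate left out in turn, where the remaining array of a group is assumed to vary like the others. Fits within a series compare arms of 1 or 2 arrays, split all groups by series and take the spread from the groups that keep 2 arrays in a series. Alternatives within a series, without the arrays that stood apart, without chromosomes X and Y, with quantile normalization and the replicate block together, by ranks for the decay, and all those of the lists on bands were added after the data were seen. Background correction by normexp and a filter on the input signal were not run, since channel signals were not used here.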

Results

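Chromosomal contacts of the mouse cytokine genes Ifng and Il4 were measured by 4C, circular chromosome conformation capture read out on a tiling array. Chromatin was crosslinked, digested with HindIII and ligated, so that DNA near a chosen gene (the bait) in the nucleus was joined to it, and the joined DNA was amplified from the bait and hybridised against digested genomic DNA. Ifng encodes interferon gamma, the signature cytokine of T helper 1 (Th1) cells, and Il4 encodes interleukin 4, the signature cytokine of T helper 2 (Th2) cells. STAT4 and STAT6 are the transcription factors that act downstream of interleukin 12 and interleukin 4 in these lineages. The title of the series names STAT binding and nuclear architecture during T cell differentiation as its subject. A total of 18 arrays in 9 groups of 2 was analysed. The Ifng bait was measured in naive CD4 T cells, Th1 cells, Th2 cells, Stat4 knockout Th1 cells and 3T3-L1, a mouse preadipocyte line derived from embryonic fibroblasts. The Il4 bait was measured in naive, Th1, Th2 and Stat6 knockout Th2 cells.

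Each array held 384942 probes with a median spacing of 5037 bp, and the number of arrays limits the precision of every value. The highest 500-kb bin lay at the bait itself, on chromosome 10 from 117500001 to 118000000 for Ifng in 10 of 10 arrays and on chromosome 11 from 53000001 to 53500000 for Il4 in 8 of 8 arrays. Its mean log2 ratio was 2.90 for Ifng (range 2.27 to 3.86) and 2.90 for Il4 (range 2.17 to 3.47). On the bait chromosome the bins of replicate arrays correlated with r between 0.830 in Il4 Th2 and 0.974 in Ifng naive cells. Off the bait chromosome the signal was weak, and r between replicates ran from 0.171 in Ifng Th1 to 0.757 in Ifng naive cells. Ifng Th1 replicate 2 had a higher r over probes with Il4 Th2 replicate 2 (0.347) than with its own replicate (0.149). A mix-up or mixture of DNA between them was not tested and is not excluded, which limits every Ifng Th1 and Il4 Th2 value, although the highest bin of both lay at the bait of its label. The labels do not say that replicates came from separate mice or cultures, so p-values measure only the spread between these arrays, which may be technical. In the 7 of 9 pairs with matching sorted values, a quantile step within the pair would also narrow that spread. The p-values may therefore be too small. At 1 to 2 Mb from the bait, Ifng Th1 (1.14 ± 0.29) and Il4 Th2 arrays (1.16 ± 0.08) had the lowest mean log2 ratio of their bait (SD, n = 2 each). The naive groups had 2.44 ± 0.20 for Ifng and 1.93 ± 0.04 for Il4. A weaker 4C library could lower the signal of Ifng Th1 and Il4 Th2 arrays, and it was not told apart from fewer contacts. The arrays read contacts and not expression, and so the loss of Stat4 or Stat6 in the knockout cells could not be checked.

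The first comparison asked where contacts of Ifng differed between Th1 and naive cells. Across chromosome 10 the Ifng signal of naive cells was stronger. It was so at 1 to 2 Mb from the bait as well (2.44 against 1.14 in Th1 cells), so a weaker Th1 library is not excluded. The region from 16500001 to 22500000 in bands 10qA2 and 10qA3, bands that hold the interferon gamma receptor gene Ifngr1, had a mean log2 ratio of 0.24 ± 0.05 in Th1 and 1.41 ± 0.000363 in naive cells (SD, n = 2 each), a change of -1.16 (SE 0.05, limma adjusted p = 7.31e-13 at its best bin). The region from 38500001 to 45500000 in 10qB1 and 10qB2, where Prdm1 for the repressor BLIMP1 lies, changed by -1.10, and the region from 57000001 to 63000000 in 10qB4, the band of the perforin gene Prf1, by -0.99. Both flanks of the bait in band 10qD2, from 114500001 to 116500000 and from 119000001 to 123000000, were also lower, by -1.13 and -1.06. The strongest gains lay on other chromosomes and were small: 0.29 on chromosome 12 from 44500001 to 45000000 (adjusted p = 0.000452), 0.25 on chromosome 1 from 146500001, 0.25 on chromosome 2 from 41000001, 0.24 on chromosome 7 from 10500001 and 0.24 on chromosome 17 from 21000001 to 22000000.

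Of 5021 bins tested between Th1 and naive cells, 590 passed, 199 higher and 391 lower in Th1. On chromosome 10, 133 of 249 bins were lower and 0 higher, while off it 199 were higher and 258 lower of 4772 (1630 of the 5021 had an unadjusted p under 0.05). The arrays differed in spread, and after division of each array by its own spread 91 bins passed, 46 higher and 45 lower, of which 73 were among the 590 with the same sign. On chromosome 10 these were 13 higher and 36 lower and off it 33 higher and 9 lower, so the balance off chromosome 10 turned. With quantile normalization 58 were higher and 187 lower. After scaling, the flank from 114500001 to 116500000 changed by -0.10 (adjusted p = 0.402) and the other flank (-0.08, adjusted p = 0.118) and the gain on chromosome 1 (0.24, adjusted p = 0.0656) no longer passed either, whereas the regions in 10qA2 to 10qA3, 10qB1 to 10qB2 and 10qB4 kept their call at -0.61, -0.53 and -0.40. The serial series as a block left 175 bins, the single series holding both groups, with 1 Th1 array, gave 200, and leaving out Th1 replicate 1, Th1 replicate 2 or naive replicate 2 gave 229, 311 and 234.

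**Figure D1:**
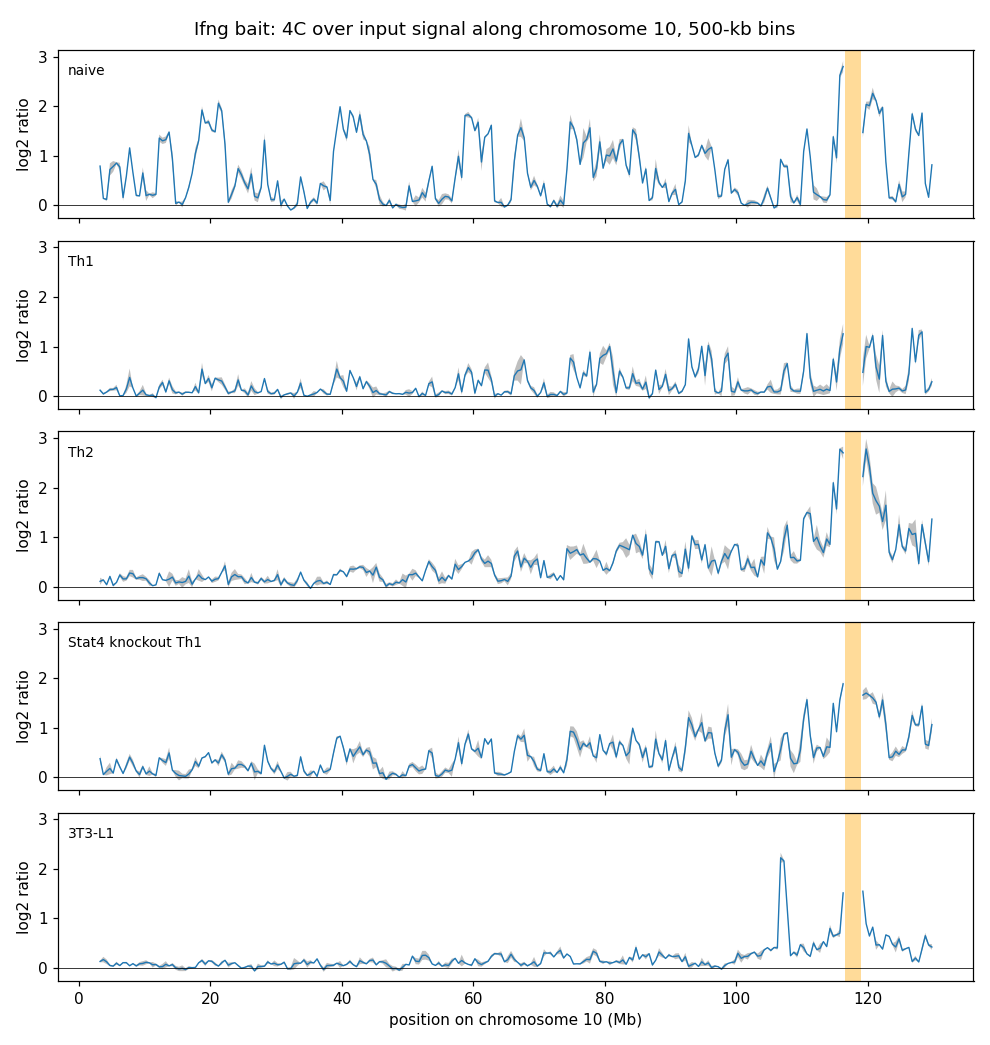
Mean log2 ratio of 4C over input DNA in 500-kb bins along chromosome 10 (position in Mb) for the 5 groups of the Ifng bait; the line is the mean of 2 replicates, the grey band their range, and the orange stripe the 1 Mb on either side of the bait that was left out. Naive cells kept peaks far from the bait, such as 1.41 from 16500001 to 22500000, where Th1 cells reached 0.24, and 3T3-L1 cells had a peak of 1.60 from 106000001 to 107500000.

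The contacts of Ifng in Th2 cells, where the gene is normally silent, were set against those in naive cells. Near the bait Th2 cells were higher. The region from 104500001 to 106500000 in 10qD1, the band of the synaptic gene Syt1, rose by 0.69 to 0.80 ± 0.05 from 0.11 ± 0.01 (SD, n = 2 each; adjusted p = 1.21e-06), and the region from 111000001 to 115500000 rose by 0.66 to 1.15 ± 0.11. Farther out Th2 cells were lower, by -1.31 from 17000001 to 22500000 (to 0.19 ± 0.04, adjusted p = 2.32e-13), by -1.21 from 38500001 to 44500000, by -1.08 from 92500001 to 93000000 and by -0.99 from 58500001 to 63000000. The regions in 10qA2 to 10qA3, 10qB1 to 10qB2 and 10qB4 that were lower in Th1 cells thus overlapped those lower in Th2 cells, although both changes share the naive arrays. With limma 251 of 5021 bins passed, 81 higher and 170 lower, with 56 higher and 91 lower on chromosome 10. Scaling left 89 bins, all of them among the 251 with the same sign, and the flank from 119000001 to 120500000, which rose by 0.64, then had a larger change of 1.06 but missed the threshold (adjusted p = 0.0546). No serial series held both groups, so no value within a series could be had, and the series as a block left 101 bins. In that fit naive and Th2 arrays are linked only through the 2 Th1 arrays, which lie in different series. Their r off the bait chromosome was 0.171, so the 101 bins do not tell series and cell type apart.

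Between the lineages, Ifng contacts were lower in Th1 than in Th2 cells over most of the distal part of chromosome 10. Th1 arrays were also lower at 1 to 2 Mb from the bait (1.14 ± 0.29 against 2.69 ± 0.17), so a weaker Th1 library is not excluded. The flank from 119000001 to 122000000 had 0.77 ± 0.27 in Th1 and 2.11 ± 0.30 in Th2 cells (SD, n = 2 each), a change of -1.34 (adjusted p = 5.48e-08), and the 26 bins from 103500001 to 116500000 changed by -0.74. The whole band 10qD2, which holds Ifng and the interleukin 22 gene Il22, stood at 0.52 ± 0.19 in Th1, 1.56 ± 0.17 in Th2 and 1.19 ± 0.05 in naive cells, without the bins next to the bait. Band 10qD3, which holds Stat6, was lower as a whole (-0.44, adjusted p = 0.00390), but not after scaling (-0.11, adjusted p = 0.554). The regions from 122500001 to 126500000 (-0.76) and from 128500001 to 130000000 (-0.75) kept their call after scaling, at -0.60 and -0.62. A few bins were higher in Th1 cells: by 0.78 from 92500001 to 93000000 (adjusted p = 3.97e-05), by 0.76 from 127500001 to 128000000 in 10qD3, by 0.64 from 95500001 to 96000000 and by 0.55 from 79500001 to 81000000. Of 133 bins that passed in limma, 12 were higher and 121 lower, and off chromosome 10 the count was 1 higher and 26 lower. With the whole bait chromosome left out 0 of 4772 bins passed, although 779 of the 5021 had an unadjusted p under 0.05. Scaling gave 22 higher and 39 lower (7 and 1 off chromosome 10, so turned there) and quantile normalization 22 higher and 64 lower, the band 10qD2 changed by -0.68 after scaling (adjusted p = 0.138), and leaving out Th1 replicate 2 gave 76 bins. The series as a block gave 90 bins, and the single series with both groups, with 1 Th1 array, 89.

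In Stat4 knockout cells the Ifng contacts near the bait were higher than in Th1 cells. At 1 to 2 Mb the knockout arrays had 1.87 ± 0.04 against 1.14 ± 0.29 in Th1 cells, so a weaker Th1 library is not excluded here either. The region from 121000001 to 122000000 reached 1.37 ± 0.08 against 0.47 ± 0.37 (SD, n = 2 each), a gain of 0.90 (adjusted p = 0.000439), and the region from 119000001 to 120500000 gained 0.85. Band 10qD3 gained 0.63 from 128500001 to 130000000, and the other flank gained 0.54 from 112000001 to 116500000. A single bin, from 80000001 to 80500000 in 10qC1, was lower, by -0.39 (0.47 ± 0.07 against 0.86 ± 0.10, adjusted p = 0.0154). In limma 95 bins passed, 94 higher and 1 lower, with 69 higher and 1 lower on chromosome 10. Scaling gave 2 higher and 7 lower, with 3 of the 95 kept, quantile normalization gave 21 higher and 10 lower, and after scaling none of the 5 regions with the largest gains passed, at changes of 0.59, 0.33, 0.50, 0.26 and 0.39 (lowest adjusted p 0.0664). The knockout arrays came from a serial series of their own, so batch and genotype cannot be told apart, and leaving out Th1 replicate 2 or knockout replicate 2 gave 30 and 57 bins.

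The 3T3-L1 line served as a cell type in which neither cytokine is in use, and was set against the naive, Th1 and Th2 arrays together (2 against 6 arrays). Its Ifng contacts formed a separate peak from 106000001 to 107500000, at 1.60 ± 0.04 against 0.47 ± 0.20 in T cells, a gain of 1.12 (adjusted p = 2.91e-10). Other gains lay on chromosome 16 from 9000001 to 10000000 (0.37, in 16qA1, the band of Socs1) and from 61500001 to 64000000 (0.34), and on chromosomes 6 and 4 (0.37 each). Losses lay on chromosome 10, by -1.15 from 110500001 to 111000000 (adjusted p = 8.57e-12), by -1.12 from 122000001 to 122500000, by -1.06 from 120000001 to 121000000, by -1.05 from 126500001 to 128500000 and by -0.86 from 58500001 to 60000000 in 10qB4. In the last of these the T cell arrays were mixed (0.94 ± 0.67, SD, n = 6). From 58500001 to 63000000 naive cells stood at 1.55 and Th2 cells at 0.56. At 1 to 2 Mb from the bait 3T3-L1 arrays had 1.55, against 2.44 in naive, 1.14 in Th1 and 2.69 in Th2 cells. A weaker 3T3-L1 library is thus not excluded for these losses. With limma 615 bins passed, 334 higher and 281 lower, with 313 higher and 147 lower off chromosome 10. Of the 615, 571 were also called with quantile normalization and 469 with scaling, which gave 388 higher and 160 lower. Leaving out 3T3-L1 replicate 1 or 2 gave 222 (108 higher, 114 lower) and 264 bins (126 and 138), and leaving out naive replicate 1 gave 728 (358 and 370), each with more lower than higher bins. The line lay in serial series of its own, so batch and cell type cannot be told apart.

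For Il4, Th1 cells differed from naive cells in few bins. The regions from 104500001 to 105000000, from 105500001 to 106000000 and from 107500001 to 109000000 of chromosome 11, in band 11qE1, were lower by -0.67, -0.69 and -0.68. At the second of these the means were 0.47 ± 0.08 in Th1 and 1.16 ± 0.01 in naive cells (SD, n = 2 each, adjusted p = 0.00305). The bin from 121000001 to 121500000 in 11qE2, the band of the cytokine signalling inhibitor Socs3, was lower by -0.47. In limma 6 of 5021 bins passed, all lower and all on chromosome 11, and 256 had an unadjusted p under 0.05. Quantile normalization called 42 bins, the 6 included, and scaling 1 and none of the 6, although the 4 regions then changed by more, by -0.88, -0.86, -0.84 and -0.58. The serial series as a block and the single series with both groups, with 1 naive array, gave 0 each. Leaving out Th1 replicate 2, Th1 replicate 1 or naive replicate 2 gave 86, 3 and 1.

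Contacts of Il4 in Th2 cells, where it is expressed, were lower than in naive cells along chromosome 11. Th2 arrays were also lower at 1 to 2 Mb from the bait (1.16 ± 0.08 against 1.93 ± 0.04), so a weaker Th2 library is not excluded. The flank from 54500001 to 55500000, in band 11qB1.3 with Il4, Il5 and Il13 of the Th2 cytokine locus, fell by 1.05 to 0.93 ± 0.06 from 1.98 ± 0.10 (SD, n = 2 each; adjusted p = 0.00631). Regions from 79000001 to 80500000 (-0.95, adjusted p = 6.42e-05), 67500001 to 68500000 (-0.95), 34000001 to 35000000 (-0.94) and 57000001 to 62000000 (-0.93) followed. Band 11qD, which holds Tbx21 for the Th1 factor T-bet, stood at 0.21 ± 0.02 in Th2 and 0.77 ± 0.08 in naive cells, a change of -0.56 (adjusted p = 0.0129, and -0.54 with 0.231 after scaling). With limma 112 bins passed, all lower, 111 of them on chromosome 11. After scaling 49 bins passed, 41 of them shared, and the regions from 54500001, from 79000001 and from 34000001 did not, at changes of -0.89, -0.98 and -0.97 that were about as large as before (adjusted p = 0.0691, 0.0629 and 0.0560). The series as a block gave 65 bins and the separate series, each with 1 naive and 1 Th2 array, 58 and 22, and leaving out naive replicate 2, Th2 replicate 1 or Th2 replicate 2 gave 48, 62 and 57.

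**Figure D2:**
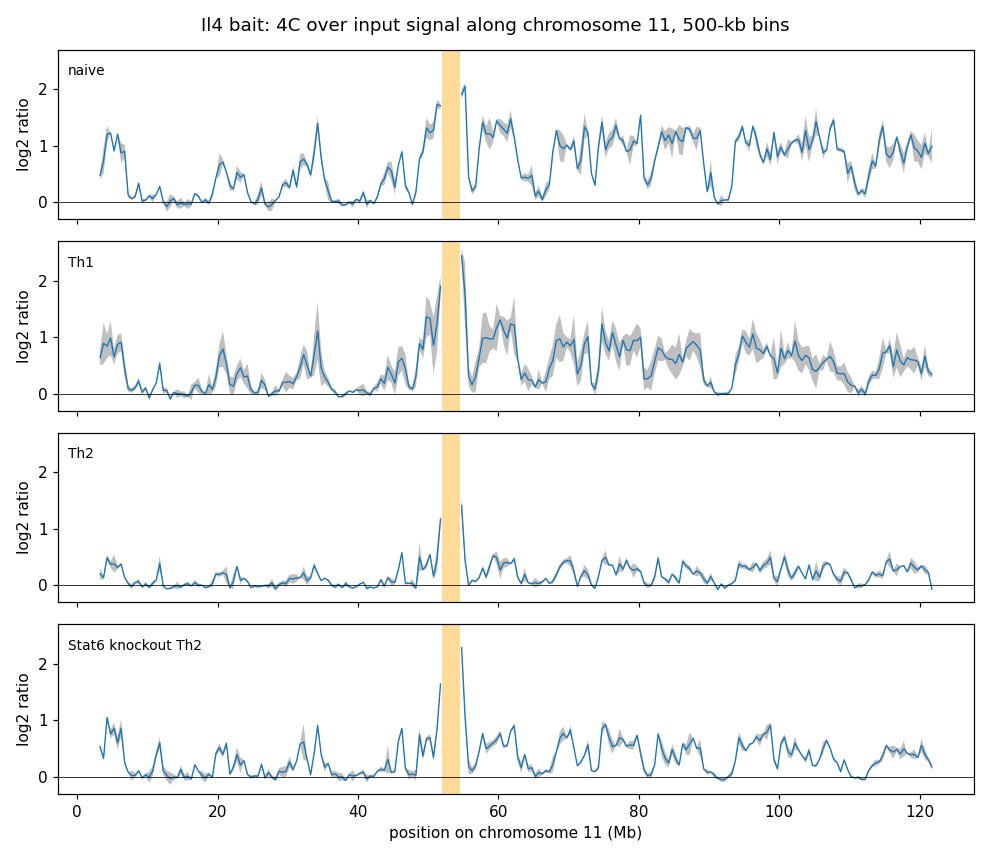
Mean log2 ratio of 4C over input DNA in 500-kb bins along chromosome 11 (position in Mb) for the 4 groups of the Il4 bait; the line is the mean of 2 replicates, the grey band their range, and the orange stripe the 1 Mb on either side of the bait that was left out. The flank from 54500001 to 55500000 stood at 1.98 in naive and 0.93 in Th2 cells.

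Between Th2 and Th1 cells the Il4 contacts were lower in Th2. The same held at 1 to 2 Mb from the bait (1.16 ± 0.08 against 2.21 ± 0.33), so a weaker Th2 library is not excluded. The bin from 60000001 to 60500000 stood at 0.27 ± 0.21 in Th2 and 1.31 ± 0.10 in Th1 cells (SD, n = 2 each), a change of -1.03 (adjusted p = 0.00260), and the bin from 54500001 to 55000000, next to the bait, at 1.41 ± 0.21 and 2.44 ± 0.18. Other bins were lower by -0.85 from 61500001 to 62000000, by -0.76 from 80000001 to 80500000 and by -0.73 from 87500001 to 88000000 in 11qC, the band of the chemokine genes Ccl3, Ccl4 and Ccl5. In limma 11 bins passed, all lower and all on chromosome 11, with 317 at an unadjusted p under 0.05. Quantile normalization kept 3 of them and scaling called 0, at changes of -0.80, -0.27, -0.61, -0.59 and -0.57 in the 5 bins (adjusted p = 0.988 for each of the 5), and the serial series as a block left 2 and the single series with both groups, with 1 Th2 array, 3. Leaving out Th1 replicate 1 gave 115 bins, and leaving out Th2 replicate 1 or 2 gave 2 and 5.

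Stat6 knockout cells under Th2 conditions differed from Th2 cells at the bait's flank, where the bin from 54500001 to 55000000 reached 2.29 ± 0.06 against 1.41 ± 0.21 (SD, n = 2 each), a gain of 0.88 (adjusted p = 0.0240). That bin was the only 1 of 5021 to pass in limma, while 382 had an unadjusted p under 0.05. Next came a bin on chromosome 12 from 21000001 (0.37, adjusted p = 0.0748) and a bin on the X chromosome from 52000001 (0.35, adjusted p = 0.0888). The lower bins with the smallest p, -0.24 on the Y chromosome from 500001, -0.24 on chromosome 14 from 52500001 and -0.16 on chromosome 6 from 8500001, did not pass. The flank's change turned to -0.04 after scaling, and no bin passed there, with quantile normalization, or without Th2 replicate 2 or either knockout replicate (0 each), while a fit of these 2 groups alone called 45 bins, all higher. The knockout arrays lay in a serial series of their own, so batch and genotype cannot be told apart. At 1 to 2 Mb from the bait they had 1.87 ± 0.02 against 1.16 ± 0.08 in Th2 cells, so a weaker Th2 library is not excluded.

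Whether the change from Th1 to Th2 differed between the baits was tested as an interaction over the bins measured with both. In the same bins, the Th2 minus Th1 change was more positive with the Ifng bait than with the Il4 bait. The difference was 1.38 from 119000001 to 122000000 of chromosome 10 (SE 0.18, adjusted p = 9.00e-06) and 1.05 from 111000001 to 116500000. With the Il4 bait, band 10qD2 of chromosome 10 stood at only 0.03 in Th1 and 0.02 in Th2 cells. The difference there thus largely restates the change of the Ifng bait. Beside Il4, on chromosome 11 from 54500001 to 55500000, the difference was 1.25 (adjusted p = 8.02e-05). It was negative from 127500001 to 128000000 of chromosome 10 (-0.73), from 80500001 to 81000000 (-0.72) and from 92500001 to 93000000 (-0.67). In limma 175 of 5016 bins passed, 170 positive and 5 negative, with 125 positive and 5 negative on chromosomes 10 and 11, and without these chromosomes 2 passed. At 1 to 2 Mb from the bait, Ifng Th1 (1.14 ± 0.29) and Il4 Th2 arrays (1.16 ± 0.08) had the lowest signal of their bait. A weaker library in either group would raise this difference and is not excluded. The possible mix-up of Ifng Th1 replicate 2 with Il4 Th2 replicate 2 enters here as well. Scaling gave 26 positive and 11 negative and quantile normalization 47 and 12, and with scaling the flank beside Il4 (0.67, adjusted p = 0.296) and that of Ifng from 119000001 (0.82, adjusted p = 0.0850) did not pass, while the largest of the named differences was then -1.52, from 127500001 to 128000000. The serial series as a block gave 87 bins and the single series with all 4 groups, with 1 Ifng Th1 and 1 Il4 Th2 array, 72. Leaving out a replicate moved the count by over 1.5 times for Ifng Th1 replicate 2 (93), Il4 Th2 replicates 1 and 2 (102 and 96), and for Ifng Th2 replicates 1 and 2 (113 each).

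Decay of the signal with distance was followed on the bait chromosome in each array. In naive cells the mean log2 ratio of Ifng contacts was 2.44 ± 0.20 at 1 to 2 Mb from the bait and 0.67 ± 0.00185 beyond 50 Mb (SD, n = 2), so that 27.7% ± 2.29 of the near signal was kept, although at 5 to 10 and 10 to 20 Mb naive cells kept less (22.0% and 16.1%) than every other T cell group, such as Th2 cells (33.9% and 25.1%). The share was 14.1% ± 0.495 in Th1, 8.02% ± 0.428 in Th2, 14.6% ± 1.16 in Stat4 knockout and 5.82% ± 0.129 in 3T3-L1 cells. For Il4 it was 44.3% ± 6.50 in naive, 19.5% ± 6.04 in Th1, 17.4% ± 0.535 in Th2 and 15.6% ± 1.68 in Stat6 knockout cells. No test of these shares was planned or run, and an exact permutation test of 2 against 2 arrays would give p = 0.333 at the least. Within each serial series that held naive and other T cell arrays of a bait, the lowest naive share was 1.80, 2.87 and 1.67 times the highest other, each time with a single naive or a single other array on a side. With medians in place of means the naive share no longer led, at 5.21% ± 0.435 against 5.92% ± 3.17 in Th1 for Ifng and 19.4% ± 9.53 against 22.3% ± 16.4 in Th2 for Il4. The median at 1 to 2 Mb, by which these shares are divided, was only 0.245 in Ifng Th1 replicate 2 and 0.31 in Il4 Th2 replicate 2. Undivided, the median beyond 50 Mb was highest in naive cells for both baits (0.145 against 0.035 in Ifng Th1, 0.42 against 0.095 in Il4 Th2).

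**Figure D3:**
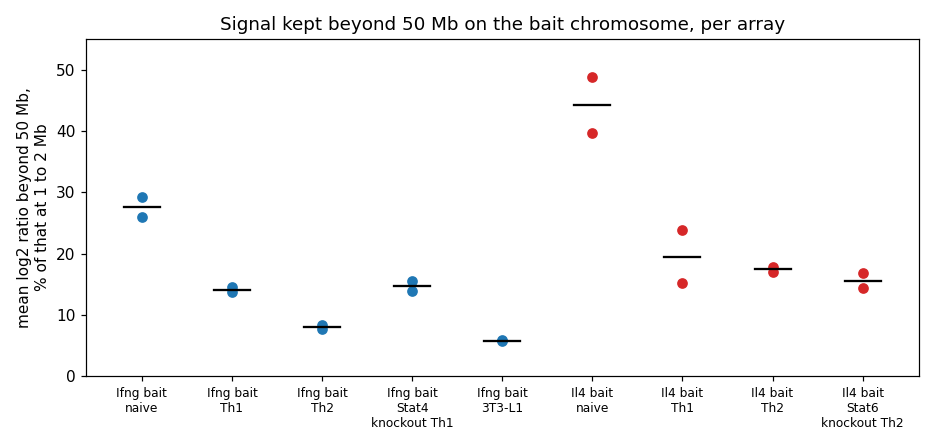
Percent of the mean log2 ratio at 1 to 2 Mb that is kept beyond 50 Mb on the bait chromosome, a point per array and a bar for the mean of the 2 replicates, with Ifng in blue and Il4 in red. The naive groups have means of 27.7% and 44.3%, above the other groups of their bait.

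Contacts with other chromosomes were called per array by ranks, as bins with an excess of the highest 5% of probes in both replicates. The Ifng bait gave 33 such bins in naive cells, 26 in 3T3-L1, 1 in Stat4 knockout and 0 in Th1 and Th2 cells, in each of which no array had more than 2. The Il4 bait gave 8 in naive, 3 in Th1, 1 in Th2 and 2 in Stat6 knockout cells, an order that turned with the highest 10% of probes, at 3, 18, 1 and 21. The Il4 naive arrays were unequal, with 10 calls in replicate 1 and 263 in replicate 2. The naive groups of both baits shared 2 bins (0.0565 by chance), the naive Ifng bins held both of the Stat6 knockout Il4 bins (0.0141 by chance) and the 1 of Stat4 knockout, and 3T3-L1 shared 0 with any T cell group, where at most 0.184 was due by chance. Of the 33 naive Ifng bins 22 lay in bands without Giemsa stain, the gene-rich part of the genome, which is 66.7% against 42.1% of all bins, whereas 15.4% of the 3T3-L1 bins did. These calls describe arrays and are no test of a condition, since neighbouring probes are not independent. Nor need they be particular to the bait. Over bins off chromosomes 10, 11 and Y, Ifng naive replicate 2 had a higher r with Il4 naive replicate 2 (0.830) than with its own replicate (0.754). Requiring an adjusted p of 0.01 left 9 naive Ifng bins and 0 shared, 200-kb bins left 8 and 0, and a call in either replicate gave 228 and 74.

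A pair of changes that share no array was compared over bins off the bait chromosome. For Ifng, the Th1 minus Th2 change and the Stat4 knockout minus naive change had r = 0.356 (jackknife SE 0.0191, 4767 bins), and for Il4 the Th2 minus Th1 and Stat6 knockout minus naive changes had r = 0.0980 (SE 0.0428, 4783 bins). Bins are not independent replicates. Adjusting for the mean over all arrays took the Ifng value to 0.0822, and leaving out naive replicate 2 to 0.197. The Il4 value turned to -0.176 without naive replicate 2 and to -0.102 without Stat6 knockout replicate 2, and was 0.342 without naive replicate 1, 0.214 without knockout replicate 1 and 0.0434 without Th1 replicate 1.

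Genes fixed as landmarks were read through their cytogenetic bands, since no annotation of the array's build was used here. In Ifng contacts of Th1 against naive cells the band of Il4 (11qB1.3) was lower by -0.08 (adjusted p = 0.00925) and that of Maf, a Th2 factor, by -0.08 (0.0419), and neither passed after scaling (-0.02 with 0.270 and -0.01 with 0.806). The bands of Stat4 and of the interleukin 12 receptor gene Il12rb2 rose by 0.07 (0.0216) and 0.06 (0.0332) and passed after scaling as well (0.0169 and 0.0406). Of all 383 bands 115 were higher and 57 lower in that comparison. In the same order, Th2 against naive cells gave 0.03 and 0.05, which did not pass, and Stat4 knockout against Th1 cells -0.00539 and 0.00764. Between Th1 and naive cells the band of Ifng itself changed by -0.67 (0.00127, and -0.03 with 0.921 after scaling) and that of Stat6 by -0.33 (0.00419, and 0.20 with 0.203 after scaling). In Il4 contacts the band of Il4 itself changed by -0.80 between Th2 and naive cells and did not pass (adjusted p = 0.0687), and the band of Ifng changed by -0.01 between Th2 and Th1 cells (0.882). Tbx21, Gata3 and Il4ra bands did not pass in any Ifng comparison, and the Runx3 gene lay too near the edge of its band to be placed.

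Gene lists were tested as sets of bands, a level chosen after the data were seen, with camera, 55 tests for Ifng and 44 for Il4. In Ifng contacts of Th1 against naive cells the Th2 programme list was lower (17 bands, median -0.05 against 0.03 in other bands, adjusted p = 0.0257), with 6 bands lower and 0 higher, and 4 lower adjusted over the list alone. Over all 383 bands 57 were lower and 115 higher. Genes of the JAK-STAT and SOCS list (16 bands, 5 lower and 1 higher, the same adjusted over the list alone; adjusted p = 0.0308) and housekeeping genes (14 bands, 6 lower and 0 higher, the same adjusted over the list alone; 0.0380) were lower too. All 3 were lost with an estimated correlation, at an adjusted p = 0.496. Between Th1 and Th2 cells the housekeeping list was lower (2 bands lower, 7 adjusted over the list alone; 0.0308), and in Stat4 knockout against Th1 cells the Th2 programme was higher (1 band higher, 4 adjusted over the list alone; 0.0443), with an adjusted p = 0.496 and 0.536 with an estimated correlation. Those 2 bands and that 1 band lay on chromosome 10. Of all 383 bands 8 were lower and 0 higher between Th1 and Th2, and 15 higher and 0 lower in Stat4 knockout. With bands off chromosome 10 alone 13 of the 55 Ifng tests passed. For Il4, the Th1 programme was lower in Th2 than in naive cells (2 bands lower, 3 adjusted over the list alone), and the Th1 programme, naive and pan-T, activation and cell cycle, and housekeeping lists were lower in Th2 than in Th1 cells, where 0 bands of any of them passed over all bands and 3, 2, 1 and 0 adjusted over the list alone. Each of these 5 had an adjusted p = 0.0376, and an adjusted p = 0.914 with an estimated correlation. With bands off chromosome 11 alone none of the 5 passed (adjusted p from 0.212 to 0.844). The Th17 and Treg, fibroblast and adipocyte, B cell, myeloid and NK, and neuronal lists did not pass in any comparison (lowest adjusted p 0.0842, 0.207, 0.0571, 0.0595 and 0.0709). No list passed after scaling or after removal of gene density, 0 of the 5 first called for Ifng stayed without Th1 replicate 1 and 0 of the 5 for Il4 without naive replicate 2, Th2 replicate 2 or either Stat6 knockout replicate. Leaving out naive replicate 1 gave 24 Ifng and 14 Il4 calls, leaving out Ifng Th1 replicate 2 or Th2 replicate 2 gave 9 each, and leaving out Il4 Th2 replicate 1 gave 2.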

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

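The test of the bait difference was planned, those of contacts that differ between naive and Th1 cells and of the dynamic range behind the naive signal at a distance were written before their results were seen, and the other tests of explanations were chosen after.

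A difference between the baits drew attention first: the Th2 minus Th1 change differed in 175 bins by the interaction test, 170 of them more positive for Ifng, and in 2 bins without chromosomes 10 and 11. These differences largely restate the change of a bait on its own chromosome, such as -1.34 between Th1 and Th2 for Ifng at the region named next. Among the named regions it was largest next to Ifng on chromosome 10 from 119000001 to 122000000 (1.38) and next to Il4 on chromosome 11 from 54500001 to 55500000 (1.25). After scaling 26 bins were positive and 11 negative, these regions had 0.82 (adjusted p = 0.0850) and 0.67 (0.296), and the largest of the named differences was -1.52, on chromosome 10 from 127500001 to 128000000. Weaker libraries of the Ifng Th1 and Il4 Th2 arrays would each push the difference towards positive values and are not excluded.

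Bins off chromosome 10 called between Th1 and naive cells with the Ifng bait were weighed against the dynamic range of the arrays. After division by each array's spread 8.10% of the 457 calls stayed with the same sign, against 75.4% of the calls between 3T3-L1 and T cells. Their mean absolute change went from 0.204 to 0.148 at a median SE of 0.0495 and 0.0520, and 3 turned sign, so the dynamic range may have enlarged the changes but was not shown to have made them, and this explanation stays open. A difference of contacts between the cell types would likely appear with the Il4 bait as well, but the changes of both baits had r = -0.157 after scaling (4529 bins). That value decides nothing, since leaving out Il4 naive replicate 1 turned it to 0.171.

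Naive arrays of both baits kept more of the mean signal near the bait beyond 50 Mb. Medians did not show this lead (5.21% against 5.92% ± 3.17 in Th1 for Ifng, 19.4% against 22.3% ± 16.4 in Th2 for Il4), but the wide SDs mean that they do not contradict it either. By ranks within an array, which cancel the dynamic range, every naive array stood above every other T cell array of its bait beyond 50 Mb. For Ifng the smallest gap was 6.69 percentage points, so dynamic range alone is not likely to explain the Ifng lead. For Il4 the smallest gap was 2.30 points, below the SD of the 2 naive arrays (6.33), so dynamic range stays open there. Within a serial series the lowest naive share was at least 1.67 times the highest other share, but each series held a single naive or a single other array and the knockouts had a series of their own, so the serial series stays open. Weaker libraries in the other groups were set against the rank lead at 1 to 2 Mb. For Ifng it was 6.39 points, within the SD of the other arrays (9.25), but a weak array, Th1 replicate 2 at 68.2%, widens that SD. The 2 other arrays that reached the lowest naive array there stayed 6.69 points or more below the naive arrays beyond 50 Mb. That speaks against weak libraries as the whole cause for Ifng, but it rests on 2 arrays and does not exclude them. For Il4 the lead was 7.21 points, also within the SD of the other arrays. There the gap of 2.30 points lay below the naive SD of 6.33, and this explanation stays open. A chromatin state of naive cells could also produce the pattern and was not tested.

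Chromosome X stood higher in replicate 2 of both knockout groups, at 0.181 in Stat4 and 0.179 in Stat6 knockout cells, against -0.0811 to 0.0550 in 12 other T cell arrays, and Stat4 knockout replicate 1 lay just above these at 0.0654. A 4C sample and an input from mice of different sex could raise X and lower Y, although the labels give the input as DNA of the same cells. The mean over the Y bins was -0.0965 in the Stat4 array (SD over bins 0.110), the direction a difference of sex would give, but its size was not tested. In the Stat6 array it was 0.150, which speaks against a difference of sex there (0.0713 to 0.306 in the 12 arrays, 5 bins). Stat6 knockout replicate 1 had a low Y mean of -0.0535 with X at 0.0322, so X and Y did not move together in that group. By the labels, loss of the Stat gene is shared by both replicates of a knockout group. It alone would not give the gap between replicates, 0.0654 against 0.181 in Stat4 and 0.0322 against 0.179 in Stat6 knockout cells. These values argue against it as the sole cause, and a smaller part of it was not tested.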

How the results depend on the processing

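The alternatives within a serial series, without the arrays that stand apart, without chromosomes X and Y, with quantile normalization and the replicate block together, by ranks for the decay, and all tests of lists on bands were chosen after seeing the data, and the other alternatives of this part before. Of 202 alternative counts of called bins 86 stayed within 1.5 times the value first given, 108 moved and 8 turned direction, and of 142 values of the 71 called named regions under quantile normalization and scaling 112 kept their call, 29 lost it with the same sign, some of them at a larger change, and 1 turned. Leaving out chromosomes X and Y changed none of 10 counts beyond that range. Weak signal off the bait chromosome and 2 arrays per group limit all of them, and except where fewer arrays or bins enter, the cause was not tested.

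Counts are given in the order Ifng Th1 against naive, Th2 against naive, Th1 against Th2, Stat4 knockout, 3T3-L1, then Il4 Th1 against naive, Th2 against naive, Th2 against Th1, Stat6 knockout and the bait difference, with those that stayed within range left out. Scaling gave 91 (46 higher, 45 lower), 89, 61 and 9 (2 and 7) for the first 4 of Ifng, 1, 49, 0 and 0 for Il4 and 37 for the bait difference, and the Stat6 knockout region on chromosome 11 from 54500001 turned to -0.0409. Quantile normalization gave 245, 156, 86 and 31 for Ifng, 42 for Il4 Th1 against naive, 3 for Th2 against Th1, 0 for Stat6 knockout and 59 for the bait difference. With the replicate block added these were 219, 151, 82, 30, 38, 0, 0 and 58. Medians per bin gave 299, 75, 70, 5 and 279 for Ifng, 24, 57, 0 and 0 for Il4 and 13 for the bait difference. The share of the highest probes gave 0, 4, 0, 0 and 148, then 0 in all 4 of Il4, and 1.

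Bins of 1000 kb gave 701 (382 higher, 319 lower, direction turned) for Ifng Th1 against naive, and for Il4 60 in Th2 against naive, 2 in Th2 against Th1 and 0 in Stat6 knockout. Bins of 200 kb gave 381 for Ifng Th2 against naive, 57 for Stat4 knockout, 619 (309 and 310, direction turned) for 3T3-L1, and 18 and 199 for Il4 Th1 and Th2 against naive. Trend and robust settings gave 908 (485 and 423, direction turned) for Ifng Th1 against naive, 47 for Stat4 knockout, and 0, 61, 1 and 2 for Il4. Without the bait chromosome 83, 0 and 19 bins were called in Ifng Th2 against naive, Th1 against Th2 and Stat4 knockout, 0, 0, 0 and 2 in the 4 of Il4, and 2 in the bait difference. Without extreme probes Ifng Th1 against Th2 gave 84, Stat4 knockout 146 and Il4 Th1 against naive 2. Only the compared groups in the fit gave 1 for Il4 Th1 against naive and 45 for Stat6 knockout.

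The serial series as a block gave 175 and 101 for Ifng Th1 and Th2 against naive, 0, 65 and 2 for the first 3 of Il4, and 87 for the bait difference. The 101 rests on the 2 Ifng Th1 arrays as the only link between series, and does not tell series and cell type apart. Within series 31, Ifng Th1 against naive gave 200 and Il4 Th2 against naive 58. Within series 40, Il4 gave 0, 22 and 3 and the bait difference 72. Without the arrays that stand apart, Ifng Th1 against naive gave 229 and Stat6 knockout 0. Replicate numbers share only a number, and deviations of equal numbers from their groups had a median r of -0.0672 over 10 Ifng pairs and -0.0142 over 6 Il4 pairs. With the number as a block Il4 Th1 against naive gave 2, Th2 against Th1 20 and Stat6 knockout 0, and no other count moved.

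With each replicate left out in turn, which assumes that a lone array varies like the others, counts ran from 229 to 705 for Ifng Th1 against naive, 76 to 112 for Th1 against Th2, 30 to 135 for Stat4 knockout, 222 (108 and 114) to 728 (358 and 370) for 3T3-L1, where 264 (126 and 138) also turned, 1 to 86, 48 to 105, 2 to 115 and 0 to 1 for Il4, and 93 to 253 for the bait difference. List calls ran from 0 to 24 for Ifng and 0 to 14 for Il4. Correlations ran from 0.197 to 0.418 for Ifng and from -0.176 to 0.342 for Il4, which also turned at -0.102.

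List calls were 5 for Ifng and 5 for Il4, 13 and 0 with bands off the bait chromosome, 29 and 0 with fry, and 0 and 0 with an estimated correlation, with scaling and with gene density removed. Contact bins in Ifng naive, 3T3-L1 and Il4 naive cells were 50, 51 and 3 with the highest 10% of probes, where Il4 Th1 had 18 and Stat6 knockout 21, and 228, 95 and 265 in either replicate with 74 shared. Bins of 200 kb gave 8, 11 and 0 with 0 shared, the threshold of 0.01 gave 9 in Ifng naive and 2 in Il4 naive cells with 0 shared, and the highest 2% gave 6 in 3T3-L1 and 25 in Il4 naive cells. The Ifng correlation was 0.447 in 1000-kb bins, 0.258 in 200-kb bins, 0.262 with quantile normalization, 0.381 by Spearman and 0.0822 adjusted for the mean. The share kept beyond 50 Mb was 5.21%, 1.14% and 19.4% by medians and 31.1%, 6.16% and 56.7% by ranks in Ifng naive, 3T3-L1 and Il4 naive cells, and 4.82% in 3T3-L1 with quantile normalization. Normexp, a filter on input signal and lists on bins were not run, and extreme probes were left out in place of the filter.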

Other observations

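The values in this part come from tests and summaries chosen after the results were seen.

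Gene-rich bands had more signal in most T cell arrays. The difference between unstained and darkest Giemsa bands was 0.05 ± 0.02 in Ifng naive and 0.05 ± 0.01 in Il4 Th1 cells (SD, n = 2 each), against 0.00 ± 0.01 in Ifng Th1 and 0.01 ± 0.01 in 3T3-L1 cells. In Ifng contacts of Th1 against naive cells 12 of 20 neuronal bands were higher and 2 lower, 13 and 2 adjusted over the list alone, though the list did not pass (adjusted p = 0.180), and their median gene density was 3.74 per Mb against 14.9 for housekeeping bands. Over all 383 bands 115 were higher and 57 lower in that comparison.

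Between T cell arrays and 3T3-L1 arrays the median r over bins off chromosomes 10, 11 and Y was -0.0351 (32 pairs), from a median of -0.0869 for 3T3-L1 replicate 1 and of 0.229 for replicate 2, while T cell arrays of different baits had 0.410 (64 pairs), those of the same bait 0.375 (48 pairs) and replicates 0.510 (9 pairs). In 3T3-L1 cells chromosome 16 stood at 0.11 ± 0.01. Ifng Th1 replicate 1 had a median r of 0.0577 with the other T cell arrays, and Il4 naive replicate 1 had 0.230.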
